A study of Caenorhabditis elegans with 9 samples.

How the data were processed

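RNA from germ lines extruded from Caenorhabditis elegans on day 6 of adulthood was sequenced in 9 libraries. The worms had been moved at adulthood to 15°C or 20°C and fed bacteria carrying either an empty RNAi vector (EV) or an RNAi construct against iff-1, which encodes a homologue of the translation factor eIF5A. The 3 groups were EV at 15°C, EV at 20°C and iff-1 RNAi at 15°C, with 3 libraries each. Per the labels' protocols, libraries were made with a stranded poly-A mRNA kit and sequenced as paired 75-nt reads. Each library is named by its group and by the replicate number in its label. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

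The deposited table gives 1 FPKM value (fragments per kilobase of transcript per 1000000 mapped fragments) per gene and library, as the authors computed it. CASAVA and Cufflinks are named in the submitters' processing notes, without versions or roles. The aligner, genome build, annotation release and strand setting of the counting are not given in the sources used here. The table has 46245 genes by WormBase ID, of which 28048 are at 0 in all libraries. Symbols were matched for 43227 IDs from a name table, and 45990 IDs were found in the WBcel235 annotation from Ensembl, used here for biotypes, exonic lengths and overlaps between genes. The authors' build may differ, so these coordinates describe WBcel235 alone. Where genes overlap on opposite strands, or have near-identical copies, the values of the partners cannot be separated here and are uncertain.

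No read counts were used. Depth was estimated from low values of single-transcript genes longer than 1000 nt. The median of FPKM times length within a preset window was taken as the worth of 1 fragment. This gave an estimated depth of 34.3 to 39.9 per library, in 1000000 fragments, and the window limits what that estimate could be. Between 79.8% and 83.6% of the low values lay within 0.25 of a step of a whole multiple, without a chance level computed. That is too few to recover counts, so count models were not applied. Exact values of 0 can be failed estimates in such a table, so a gene at 0 is described as listed at 0, with no fold change.

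Changes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 8572 genes with a mean FPKM of at least 1 over the 9 libraries. All 9 libraries entered 1 fit with 6 residual degrees of freedom, with a variance trend in the empirical Bayes step. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Of the tested genes, 8062 are protein-coding, 8528 have an ID in the annotation and 8275 are printed under a symbol. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. EV at 20°C and iff-1 RNAi at 15°C were each compared with EV at 15°C, and then with each other. The SD is given over 3 libraries, and SE is limma's standard error of the log2 fold change. Values of p printed without another test's name come from limma.

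The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named as added. Of 27 lists, 24 had at least 5 tested members. They were tested with limma's camera with a preset correlation of 0.01 between genes, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, and its mixed form whether they change in either direction; neither compares a list with other genes. For each list the called members were also counted with p adjusted over the list alone. Marker lists covered intestine, body wall and sheath muscle, pharynx, cuticle, neurons, somatic gonad, early embryo, and coelomocytes with uterus or vulva. They were included because extruded gonads could carry these cells along.

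Genes were named by rule: iff-1; per comparison with EV at 15°C, the 10 called genes that rose and the 10 that fell most with no overlap between groups; 5 each way between iff-1 RNAi at 15°C and EV at 20°C; up to 4 members per list with the smallest adjusted p, whether or not they passed; and 12 genes always (glp-1, gld-1, pgl-1, cbs-1, pges-2, daf-41, fat-7, vit-2, hsp-4, pas-5, rpn-6.1 and iff-1). A gene named outside this rule was chosen after its values were seen.

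Both comparisons use the same control libraries, so their similarity was set beside 100 simulations of unchanged groups against those controls. The steps were tested on simulated data with 8572 genes and 50 genes changed at each size, 10 times per comparison. For EV at 20°C against EV at 15°C, 34.0% of genes changed by 0.25 on the log2 scale were recovered, 68.2% at 0.5, 86.2% at 1 and 94.6% at 2, and 4.73% of calls were false. For iff-1 RNAi against EV at 15°C the shares were 38.4%, 66.0%, 85.0% and 97.0%, with 4.72% false. In both, a list of 30 genes shifted by 0.3 was called in 10 of 10 simulations, and 0 of 190 unshifted lists were. The simulated genes varied independently, whereas the estimated correlation within real lists reached 0.818, for ribosomal proteins. These simulations therefore cannot tell how often the preset calls lists whose genes vary together, and smaller list shifts were not simulated.

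The alternatives were a pseudocount of 0.1; no filter, or a mean FPKM of at least 5; scaling by median ratios, by quantile normalization, or to the same sum without the 10 highest genes; no variance trend; library weights; only the groups compared; the replicate number as a block; a fold change of at least 2; and each library left out in turn. Added after the data were seen were protein-coding genes of at least 300 nt alone, and zeros of abundant genes treated as missing. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.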

Results

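Expression was measured as FPKM in 9 libraries of extruded C. elegans germ line, 3 each from worms on empty vector RNAi at 15°C (EV 15C), empty vector RNAi at 20°C (EV 20C) and iff-1 RNAi at 15°C (iff-1 RNAi 15C). The depth of a library, estimated within the limits of a preset window, was 34.3 to 39.9 (in 1000000 fragments). Between 8120 and 8932 genes reached 1 FPKM. The values of a library summed to between 973003 and 1064980 FPKM, of which the 10 highest genes held 6.78% to 9.48%. The log2 values of libraries correlated at r = 0.974 to 0.982 within groups and 0.962 to 0.979 between groups, across genes, which are not independent replicates. The median coefficient of variation within a group was 4.49% for EV 15C, 6.43% for EV 20C and 5.57% for iff-1 RNAi 15C. The first principal component, with 26.5% of the variance, placed the EV 20C libraries between 20.2 and 25.7, the EV 15C libraries between -4.33 and 0.99, and the iff-1 RNAi 15C libraries between -25.43 and -16.52.

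The RNAi target was read first. The gene iff-1 (WBGene00002064, chromosome III, 9745862 to 9747193, minus strand in WBcel235) had 2677, 2653 and 2510 FPKM in the EV 15C libraries and 2665, 2442 and 2479 FPKM in the EV 20C libraries. In the iff-1 RNAi 15C libraries it had 103.9, 58.0 and 37.4 FPKM. The mean fell from 2613 ± 90.4 to 66.4 ± 34.01 FPKM (SD, n = 3), which is 97.5% below EV 15C. The log2 fold change was -5.40 (SE 0.29, limma adjusted p = 5.47e-05). An exact two-sided permutation test of the 3 against 3 libraries gave p = 0.1, the smallest it can give. Between EV 20C and EV 15C iff-1 differed by -0.05 (adjusted p = 0.92). The gene overlaps T05G5.17 on the other strand, and the strand setting of the counting is not given. The related gene iff-2, also an eIF5A homologue, fell from 26.03 ± 0.848 to 14.7 ± 1.79 FPKM under iff-1 RNAi (log2 -0.79, adjusted p = 0.000837), and reads shared between the pair cannot be ruled out.

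The labels set EV 20C against EV 15C, which addresses how the warmer temperature changes the adult germ line transcriptome. At 20°C, the lists of DNA replication, mitotic and oogenesis genes were called higher and those of chaperonin, proteasome and translation factor genes lower with camera's preset correlation. With an estimated correlation 0 of 24 lists were called (adjusted p = 0.225 to 0.402 for these 6), and with libraries scaled without the 10 highest genes 3 proteasome subunits fell and 3 rose. The RNA regulator nos-2, of the Nanos family, rose from 125 ± 5.13 to 198 ± 2.15 FPKM (SD, n = 3; log2 0.65, SE 0.03, limma adjusted p = 9.42e-05). The targets of the GLP-1/Notch receptor that keep germ cells undifferentiated rose too: sygl-1 from 262 ± 9.78 to 345 ± 13.4 FPKM and lst-1 from 127 ± 5.12 to 169 ± 6.85 FPKM. The receptor gene glp-1 itself had 96.4 ± 2.87 FPKM at 15°C and 96.8 ± 3.29 at 20°C (adjusted p = 0.92). In all, 2401 of 8572 genes were called, 1656 higher and 745 lower, with a median absolute log2 fold change of 0.27. Changes of at least 2-fold were mostly falls, with 48 lower and 13 higher genes.

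DNA replication genes were higher at 20°C: 15 of 33 rose and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 0.000136, and adjusted p = 0.345 with an estimated correlation). The helicase subunit mcm-3 rose from 168 ± 2.24 to 196 ± 1.93 FPKM, the clamp loader subunit rfc-4 from 238 ± 2.74 to 280 ± 3.03, and the ribonucleotide reductase subunit rnr-2 from 602 ± 5.29 to 714 ± 14.2. Of 42 mitotic genes, 18 rose and 2 fell, or 24 and 4 adjusted over the list alone, 20 and 4 without iff-1 RNAi 15C replicate 3 and 16 and 5 under median ratio scaling (camera adjusted p = 0.00164, and adjusted p = 0.402 with an estimated correlation). These included the cyclin genes cyb-2.2 (log2 0.27) and cyb-3 (0.26), the kinetochore gene ndc-80 (0.27) and the centromeric histone gene hcp-3 (0.30). Of 30 oogenesis and eggshell genes, 18 rose and 1 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 4.80e-05, and adjusted p = 0.39 with an estimated correlation). The maternal zinc finger genes pie-1 (0.40), mex-1 (0.25) and oma-1 (0.22) were among them. In the list of stem cell signalling and the mitosis-meiosis decision 5 of 17 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.145). These were nos-2, sygl-1, lst-1, the RNA-binding gene mex-3 (0.20) and, named after its values were seen, fbf-1, whose adjusted p reached 0.0978 without EV 15C replicate 1.

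Transcripts of the chaperonin that folds actin and tubulin were lower at 20°C. Counts of subunits, factors and ribosomal proteins, here and later, refer to their genes, because only RNA was measured. All 8 tested subunits of the TRiC/CCT complex fell, the same adjusted over the list alone, with a median log2 fold change of -0.23 (camera adjusted p = 2.10e-08, and adjusted p = 0.225 with an estimated correlation). The subunit gene cct-5 fell most, from 544 ± 11.03 to 394 ± 10.5 FPKM. Of 33 proteasome subunits 12 fell and 1 rose, or 12 and 2 adjusted over the list alone, with a median of -0.05 (camera adjusted p = 8.07e-05, and adjusted p = 0.30 with an estimated correlation). The core subunit gene pbs-5 fell from 290 ± 6.28 to 244 ± 6.14 FPKM, but with libraries scaled without the 10 highest genes 3 subunits fell and 3 rose, and without EV 15C replicate 1 7 fell. Of 33 translation factors 14 fell and 1 rose, or 17 and 1 adjusted over the list alone (camera adjusted p = 7.26e-07, and adjusted p = 0.39 with an estimated correlation). Their median was -0.13 but their mean 0.06, because ife-3 and ifg-1 are listed at 0 in some libraries. The eIF3 subunit genes eif-3.E (-0.25), eif-3.L (-0.29) and eif-3.D (-0.23) and the termination factor gene erfa-1 (-0.28) fell. Of 80 cytosolic ribosomal proteins 10 fell and 0 rose, and adjusted over the list alone 0 passed (camera adjusted p = 1.84e-10, and adjusted p = 0.499 with an estimated correlation). The count of falls moved between 1 without EV 15C replicate 2 and 71 without EV 20C replicate 1, with 2 without EV 15C replicate 1, 2 without EV 20C replicate 3, 4 without EV 20C replicate 2 and 5 without any 1 of the iff-1 RNAi 15C libraries. Under quantile normalization 3 of them fell and 3 rose and the list was not called (adjusted p = 0.361, against a range of 3.84e-29 to 0.361 over the alternatives).

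Other germ line genes were called both ways at 20°C, as were all 8572 tested genes, with 1656 higher and 745 lower. Camera's preset called none of the lists in this paragraph, and their counts were not tested against those of all genes. Of 24 germ granule and small RNA genes, 8 fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.181). The Vasa-related helicase gene glh-1 fell from 314 ± 11.8 to 244 ± 5.58 FPKM and the Argonaute gene csr-1 from 221 ± 0.617 to 194 ± 2.47, while the germ granule gene meg-1 rose from 126 ± 2.15 to 160 ± 11.17. Of 32 meiotic genes 8 rose and 4 fell (camera adjusted p = 0.728), with the break-forming enzyme gene spo-11 higher (0.29) and the checkpoint kinase gene chk-2 lower (-0.41). These counts were 5 and 1 without any 1 of the EV 15C libraries, 8 and 1 without EV 20C replicate 2 and 6 and 2 without EV 20C replicate 3. Median ratio scaling gave 5 and 5. The sperm fate gene fog-3 fell from 5.98 ± 1.51 to 2.67 ± 0.405 FPKM (log2 -0.91, adjusted p = 0.0122). It was the only call among the 6 of 57 spermatogenesis genes that passed the filter (camera adjusted p = 0.14). Of 20 heat shock and chaperone genes 5 fell and 2 rose, or 7 and 2 adjusted over the list alone and 3 and 1 without EV 15C replicate 1, EV 15C replicate 2 or EV 20C replicate 3 (camera adjusted p = 0.14). The endoplasmic reticulum chaperone gene hsp-3 rose from 130 ± 4.98 to 197 ± 28.1 FPKM, and hsp-110 (-0.24) and the small heat shock gene hsp-12.6 (-1.55) fell. The reporter gene of endoplasmic reticulum stress, hsp-4, had 258 ± 9.04 FPKM at 15°C and 258 ± 17.4 at 20°C.

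Metabolic and stress lists were mostly not called at 20°C. In fatty acid and prostaglandin genes 2 of 22 rose and 2 fell, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.355). The prostaglandin synthase gene pges-2 fell from 139 ± 6.30 to 115 ± 5.11 FPKM (adjusted p = 0.00526), while daf-41 differed by -0.08 (adjusted p = 0.15). In transsulfuration genes 1 of 15 rose, cysl-3 (0.35), and 1 fell, ahcy-1 (-0.16; camera adjusted p = 0.917, direction lower although the median is 0.09), and 4 rose without EV 20C replicate 1. The hydrogen sulfide enzyme gene cbs-1 had 3.35 ± 0.192 FPKM at 15°C and 4.36 ± 0.46 at 20°C (adjusted p = 0.0719). Of 36 nuclear genes of oxidative phosphorylation 4 rose and 4 fell (camera adjusted p = 0.659), but 8 rose and 2 fell when scaled without the 10 highest genes and 2 rose and 5 fell under median ratio scaling. Without EV 15C replicate 1 4 rose and 2 fell, without EV 15C replicate 2 1 and 2, and without EV 20C replicate 3 2 and 2. Of 22 oxidative stress genes 3 rose and 2 fell, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.206), with the peroxiredoxin gene prdx-2 higher (0.25) and the superoxide dismutase gene sod-3 lower (-0.86). Median ratio scaling and quantile normalization gave 1 rise and 3 falls. Rises also numbered 1 without any 1 of EV 15C replicates 1, 2 and 3, EV 20C replicates 2 and 3 and iff-1 RNAi 15C replicate 2. The adjusted p of sod-2, among the rises, reached 0.131 without EV 15C replicate 3. Of 16 apoptosis genes 1 rose, the engulfment gene ced-6 (0.20; camera adjusted p = 0.355). Of 12 genes of the mitochondrial genome 8 fell and 1 rose, the cytochrome oxidase subunit gene COX3 (0.32), with a median of -0.29 (camera adjusted p = 0.00224, and adjusted p = 0.30 with an estimated correlation). The falls numbered 4 without EV 15C replicate 1, 5 without EV 15C replicate 2 and 4 without EV 20C replicate 3. Neighbouring mitochondrial genes overlap, so their single values are uncertain.

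The lists of body wall and sheath muscle, cuticle, immune and intestine genes were called lower at 20°C with the preset correlation. The neuron and somatic gonad lists were not called. The lists named 19 muscle, 26 cuticle, 30 immune, 25 intestine, 27 neuron and 15 somatic gonad genes. Of these 15, 8, 13, 15, 9 and 7 were tested. Of 15 muscle genes 3 fell, mlc-2, pat-10 and unc-68, and 0 rose, the same adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.00119, and adjusted p = 0.494 with an estimated correlation), and the myosin light chain gene mlc-2 fell from 48.6 ± 4.15 to 29.7 ± 5.88 FPKM. Muscle falls numbered 1 without EV 15C replicate 1 or EV 20C replicate 3 and 5 without EV 20C replicate 2. Without EV 20C replicate 3 the adjusted p of pat-10 reached 0.0574 and that of unc-68 reached 0.0659. Of 8 cuticle genes 2 fell, the collagen genes col-143 and col-140, with a median of -0.78 (camera adjusted p = 0.00258, and adjusted p = 0.492 with an estimated correlation). With 1 library left out the adjusted p of col-143 reached 0.0742 and that of col-140 reached 0.121, both without EV 20C replicate 3, and limma called 0 of 8 cuticle genes without EV 15C replicate 3, EV 20C replicate 1 or EV 20C replicate 3 and 5 without EV 20C replicate 2. Of 13 innate immune genes 4 fell, the antimicrobial peptide genes cnc-2 (from 3.04 ± 0.0835 to 1.061 ± 0.277 FPKM), nlp-29, cnc-4 and nlp-31, with a list median of -0.28 (camera adjusted p = 0.00885, and adjusted p = 0.499 with an estimated correlation). Of 15 intestine genes 0 passed, with a median of -0.62 (camera adjusted p = 0.0152, and adjusted p = 0.639 with an estimated correlation), and the yolk gene vit-2 had 41.12 ± 30.3 FPKM at 15°C and 23.9 ± 11.03 at 20°C. EV 15C replicate 3 stood apart within its group, with a mean log2 level of 4.85 for the intestine list against 3.59 and 3.51 in the other EV 15C libraries, and 3.31 for the immune list against 2.43 and 2.27. In EV 20C, replicate 2 stood apart too, nearer to the EV 15C libraries, with 2.431 for the cuticle list against 1.64 and 1.74, 4.003 for the intestine list against 3.11 and 3.14, and 3.47 for the muscle list against 2.94 and 3.155. Without EV 15C replicate 3 the immune list had a median of 0.20 (adjusted p = 0.393, against a range of 0.000575 to 0.393 over the alternatives) and the intestine list -0.17 (adjusted p = 0.316, against a range of 0.00122 to 0.316). With 1 library left out the adjusted p of nlp-29, cnc-4 and nlp-31 reached 0.0537, 0.0866 and 0.124, without EV 15C replicates 2, 1 and 3, and immune falls numbered 2 without any of these or EV 20C replicate 1. The intestine call was also lost without EV 20C replicate 1 (adjusted p = 0.0981). The lists of neurons (1 of 9 rose, the synaptobrevin gene snb-1) and somatic gonad (0 of 7 called) had camera adjusted p = 0.928 and 0.355.

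Among the 10 largest rises at 20°C, 7 genes are protein-coding. The saposin-like gene spp-9 had 0.162, 0.613 and 1.01 FPKM in the EV 15C libraries and 7.21, 53.6 and 22.8 in the EV 20C libraries (log2 3.82, adjusted p = 0.00285). The nuclear receptor gene nhr-70 rose from 2.09 ± 0.222 to 5.65 ± 0.715 FPKM, C33A12.4 from 0.633 ± 0.109 to 4.17 ± 1.51 and F10G2.4 from 3.45 ± 0.834 to 10.8 ± 0.681. Among the 10 largest falls, 6 are protein-coding, including dct-7 (from 7.38 ± 2.18 to 1.73 ± 0.816) and the antimicrobial peptide gene cnc-7 (from 3.28 ± 1.00 to 0.578 ± 0.405). W03D8.13, C16A3.11 and F53B6.13 are listed at 0 in all EV 20C libraries. The largest changes of other biotypes were in short small nuclear and nucleolar RNAs, which poly-A selection captures poorly.

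The share of higher genes at 20°C depended on the scaling, with 69.0% of called genes higher in the FPKM as deposited, 54.1% under median ratio scaling (1228 higher, 1041 lower), 55.3% under quantile normalization (1261 and 1021) and 77.9% when scaled without the 10 highest genes (1807 and 512). Of the called genes, 2386 had no overlap between the groups; of all genes 45.4% had none, against 10% by chance. The count fell to 1534 without EV 15C replicate 1, 1521 without EV 15C replicate 2 and 1534 without EV 20C replicate 3. With an estimated correlation 0 of 24 lists were called where camera's preset called 12, 3 higher and 9 lower; fry called 9, its mixed form 18.

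**Figure D1:**
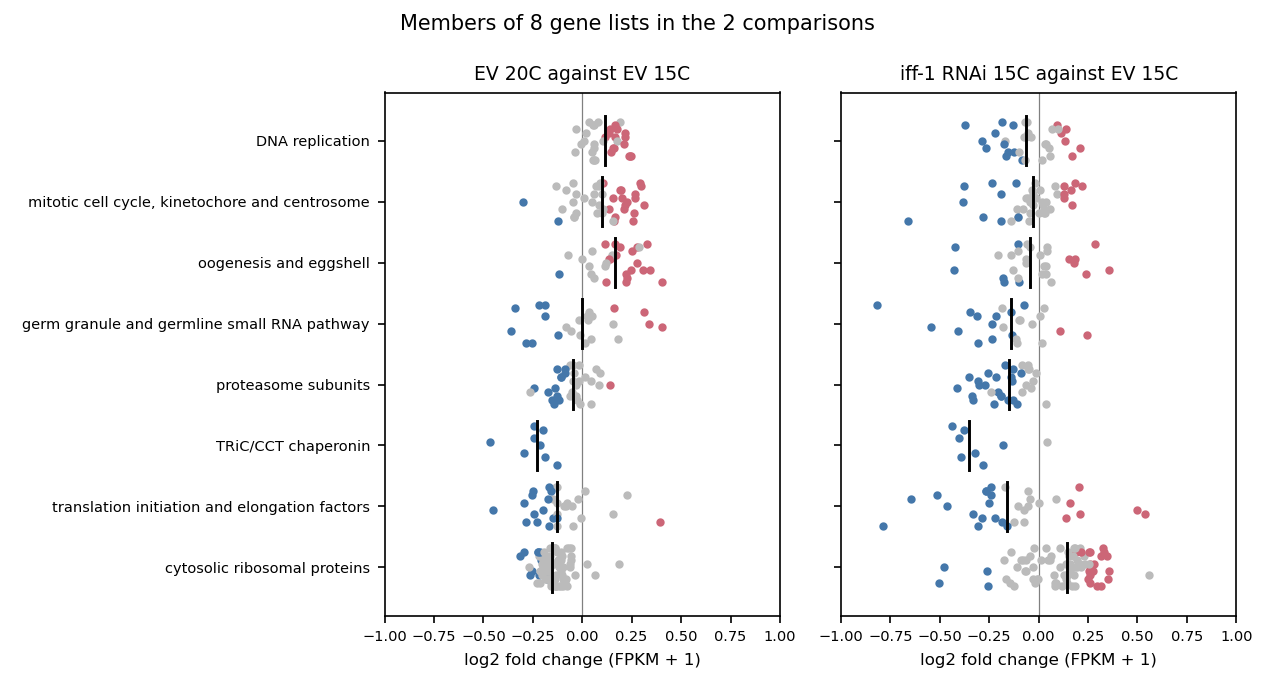
Log2 fold changes (FPKM + 1 scale) of the tested members of 8 gene lists in EV 20C against EV 15C (left) and iff-1 RNAi 15C against EV 15C (right), with 1 point per gene, called rises in red, called falls in blue, genes not called in grey and the median of the drawn members as a black bar. The 5 members listed at 0 in some library are left out; CCT members lie below 0 at 20°C, and the DNA replication median lies above 0 at 20°C and below 0 under iff-1 RNAi.

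The labels also set iff-1 RNAi 15C against EV 15C, a comparison that the series title ties to reduced proliferation of germ line stem cells. Under iff-1 RNAi, the genes fog-3 and fog-1 were higher and the mitotic kinase gene cdk-1 was lower, and the lists of germ granule, proteasome, chaperonin and translation factor genes were called lower with camera's preset correlation. None of these 4 lists was called with an estimated correlation (adjusted p = 0.815, 0.061, 0.222 and 0.927). The gene fog-3, which specifies sperm fate, rose from 5.98 ± 1.51 to 18.96 ± 4.45 FPKM (SD, n = 3; log2 1.52, SE 0.20, limma adjusted p = 0.00122), and its partner fog-1 rose from 93.9 ± 5.54 to 157 ± 15.1 FPKM. The gene snpc-1.3, whose product drives transcription of male piRNAs, rose from 7.79 ± 1.498 to 29.5 ± 8.66 FPKM, and it overlaps acl-6 on the other strand. The gene cdk-1 fell from 403 ± 3.05 to 254 ± 6.01 FPKM (log2 -0.66, SE 0.02, adjusted p = 9.28e-06). In all, 2659 of 8572 genes were called, 1370 higher and 1289 lower, with a median absolute log2 fold change of 0.26. The majority turned with the setting: 1240 were higher and 1460 lower under median ratio scaling, and 988 and 1224 when scaled without the 10 highest genes. It also turned without iff-1 RNAi 15C replicate 3 (1163 and 1398) or EV 15C replicate 3 (968 and 995). At least 2-fold changes were few, with 25 higher and 8 lower genes.

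Germ granule and small RNA genes were lower under iff-1 RNAi: of 24, 12 fell and 2 rose, or 15 and 2 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.000145, and adjusted p = 0.815 with an estimated correlation). The Vasa-related helicase genes glh-2, from 142.7 ± 3.18 to 80.8 ± 7.78 FPKM, and glh-1, from 314 ± 11.8 to 236 ± 10.1, fell, as did meg-4 (-0.54). The granule component gene pgl-1 had 378 ± 8.05 FPKM in EV 15C and 351 ± 22.2 under iff-1 RNAi (adjusted p = 0.0886). In the stem cell list 4 of 17 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.668). The gene gld-1, which promotes entry into meiosis, rose from 805 ± 3.89 to 930 ± 35.8 FPKM, with glp-1 (0.17), the Pumilio gene puf-8 (0.21) and fog-1, while nos-2, sygl-1, lst-1, fbf-2 and epn-1 fell, these 5 named after their values were seen. The adjusted p of sygl-1 and epn-1 reached 0.0506 and 0.0842 without EV 15C replicate 1, and that of lst-1 0.146 without iff-1 RNAi 15C replicate 1. In the stem cell list 4 rose and 2 fell without EV 15C replicate 1. Of 57 spermatogenesis genes on the list only 6 passed the filter on mean FPKM and were tested. Among these 6, fog-3 and, named after its values were seen, spe-41 rose and spe-5, spe-6 and spe-44 fell (camera adjusted p = 0.668, median -0.32, mean 0.13). Without EV 15C replicate 2 the adjusted p of these 3 falls reached 0.0642, 0.103 and 0.0749, and without EV 15C replicate 3 that of spe-41 reached 0.107.

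Proteasome genes were lower under iff-1 RNAi. Of 33 subunits 21 fell and 0 rose, or 23 and 0 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 3.69e-12, and adjusted p = 0.061 with an estimated correlation). The core subunit genes pas-2, from 422 ± 5.79 to 331 ± 3.87 FPKM, and pbs-5, from 290 ± 6.28 to 217 ± 3.88, and the regulatory subunit genes rpn-9 (-0.34), rpt-3 (-0.31) and rpn-6.1 (-0.14) fell. The core subunit gene pas-5 is listed at 484 FPKM in EV 15C replicate 3 and at 0 in the other 8 libraries. Of 8 CCT subunits 7 fell, the same adjusted over the list alone, with a median of -0.35 (camera adjusted p = 3.48e-06, and adjusted p = 0.222 with an estimated correlation). The gene cct-6 fell from 333 ± 3.89 to 254 ± 2.31 FPKM and cct-1 from 323 ± 4.43 to 265 ± 4.04, and cct-5, named here after its values were seen, differed by 0.04 (adjusted p = 0.383). Of 20 heat shock and chaperone genes 4 rose and 4 fell (camera adjusted p = 0.668). The co-chaperone gene sti-1 fell from 216 ± 3.91 to 132 ± 10.2 FPKM and the cytosolic Hsp70 gene hsp-1 from 2421 ± 29.7 to 1741 ± 96.3, while the organelle chaperone genes hsp-4 (0.30) and hsp-6 (0.31) rose.

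The translation factor list was called lower and the ribosomal protein list higher under iff-1 RNAi with camera's preset, without a test of 1 against the other. Of 33 translation factors 15 fell and 6 rose, the same adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.00155, and adjusted p = 0.927 with an estimated correlation). The eIF3 subunit genes eif-3.H, from 142.6 ± 2.90 to 91.0 ± 6.02 FPKM, eif-3.C (-0.46) and egl-45 (-0.22) fell. Of 80 cytosolic ribosomal proteins 19 rose and 4 fell, or 18 and 4 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.00801, and adjusted p = 0.927 with an estimated correlation). The genes rps-28 (0.35) and rla-0 (0.32) rose, and the near-identical pair rpl-41.1 (-0.48) and rpl-41.2 (-0.50) fell, each uncertain because reads of the pair may be shared. The rises numbered 3 without EV 15C replicate 1, 9 without EV 15C replicate 2, 2 without EV 15C replicate 3 (with 2 falls), 2 without iff-1 RNAi 15C replicate 1, 5 without iff-1 RNAi 15C replicate 2 and 43, with 8 falls, without EV 20C replicate 1. Under quantile normalization 22 ribosomal genes rose and 19 fell, with a median of 0.02, and the list was not called (adjusted p = 0.663, against a range of 0.000173 to 0.663 over the alternatives), nor was it without iff-1 RNAi 15C replicate 2 (adjusted p = 0.0564).

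Cell cycle lists held genes called both ways under iff-1 RNAi, as did all 8572 tested genes, with 1370 higher and 1289 lower. Camera's preset called none of the lists in this paragraph. Their counts were not tested against those of all genes, so they do not show a response of these lists. Of 33 DNA replication genes 11 fell and 6 rose, or 11 and 7 adjusted over the list alone (camera adjusted p = 0.188). With 1 library of either group left out the falls went down to 5 (without iff-1 RNAi 15C replicate 1) and the rises to 3 (without that library, EV 15C replicate 2 or EV 15C replicate 3). The clamp loader gene rfc-2 (-0.37) and the ribonucleotide reductase gene rnr-1 (-0.29) fell, and rfc-4 (0.17) and the polymerase subunit gene pole-2 (0.21) rose. Of 42 mitotic genes 9 fell and 7 rose (camera adjusted p = 0.288; 4 rises without EV 15C replicate 2 or iff-1 RNAi 15C replicate 2), with the anaphase-promoting complex gene mat-3 (-0.39) and the spindle checkpoint genes mdf-2 (-0.23) and bub-3 (-0.19) lower beside cdk-1. Of 32 meiotic genes 3 rose and 3 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.668), with the pairing gene zim-2 (0.27) and the cohesin gene rec-8 (0.16) higher. Meiotic falls numbered 1 without any 1 of the EV 15C libraries, EV 20C replicate 3 or iff-1 RNAi 15C replicate 1. Meiotic rises numbered 5 without EV 20C replicate 1 or iff-1 RNAi 15C replicate 2 and 6 under quantile normalization. Scaled without the 10 highest genes, 3 DNA replication genes rose and 9 fell, and 4 mitotic genes rose and 9 fell. Of 30 oogenesis and eggshell genes 6 rose and 6 fell, or 5 and 2 under quantile normalization (camera adjusted p = 0.739), with the chitin synthase gene chs-1 (-0.43) lower, and the translational regulator genes daz-1 (0.24), puf-6 (0.36) and puf-7 (0.29) higher, the last a similar pair whose reads may be shared. Of 16 apoptosis genes 2 rose, ced-6 and cep-1, and 1 fell, ced-8, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.89). Without EV 15C replicate 1 the adjusted p of cep-1 reached 0.133 and that of ced-8 reached 0.0894.

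Of 36 nuclear genes of oxidative phosphorylation 13 fell and 3 rose under iff-1 RNAi (camera adjusted p = 0.0713, but 0.0254 without EV 15C replicate 3 and 0.0340 without iff-1 RNAi 15C replicate 1), with the complex I genes nuo-1 (-0.25), nuo-5 (-0.22) and lpd-5 (-0.28) and the complex III gene ucr-2.3 (-0.35) lower. The mitochondrial superoxide dismutase gene sod-2 fell from 233 ± 5.80 to 180 ± 12.7 FPKM, among 4 falls and 1 rise in 22 oxidative stress genes (camera adjusted p = 0.393, median 0.06 and mean -0.01). That median was -0.01 under quantile normalization and 0.10, with 2 rises, without EV 15C replicate 3, and 2 also rose without EV 20C replicate 1. Of 15 transsulfuration genes 4 fell and 1 rose, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.226). Among them cbs-1 fell from 3.35 ± 0.192 to 1.79 ± 0.156 FPKM (adjusted p = 0.00321) and mpst-1 from 65.3 ± 0.44 to 51.6 ± 5.26, and ahcy-1 rose (0.22). Of 22 fatty acid and prostaglandin genes 4 rose and 3 fell (camera adjusted p = 0.188), with the nuclear receptor gene nhr-49 higher (0.31). By limma 2 rose and 1 fell without EV 15C replicate 2, and 0 fell without EV 15C replicate 1, iff-1 RNAi 15C replicate 1 (2 rises) or iff-1 RNAi 15C replicate 2. The genes pges-2 (-0.17, adjusted p = 0.030) and daf-41 (-0.14, adjusted p = 0.0212) fell, but their adjusted p reached 0.0985 without iff-1 RNAi 15C replicate 2 and 0.0793 without EV 15C replicate 2. The desaturase gene fat-7 was under the filter, at 0 to 0.111 FPKM. Of 12 genes of the mitochondrial genome 4 rose and 3 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.866). Of these 2 rose and 2 fell without EV 15C replicate 1. They were 2 and 1 without EV 15C replicate 2 or iff-1 RNAi 15C replicate 1.

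Muscle genes were called lower as a list under iff-1 RNAi, with 4 of 15 genes lower (cpn-3, mlc-1, mlc-2 and mup-2) and 0 higher and a median of -0.36 (camera adjusted p = 0.00494, and adjusted p = 0.927 with an estimated correlation). The gene cpn-3, a calponin of muscle, fell from 17.2 ± 1.33 to 11.5 ± 1.62 FPKM. The adjusted p of mlc-1 and mlc-2 reached 0.0867 and 0.0808 without iff-1 RNAi 15C replicate 2, that of mup-2 0.0834 without iff-1 RNAi 15C replicate 1, and that of the cuticle gene dpy-10 reached 0.12 without EV 15C replicate 3. The adjusted p of unc-64 reached 0.117 without iff-1 RNAi 15C replicate 1 and that of unc-119 0.112 without EV 15C replicate 2. The immune (0 of 13 called), intestine (0 of 15), cuticle (1 of 8 rose, dpy-10), neuron (3 of 9 rose, egl-3, unc-64 and unc-119) and somatic gonad (0 of 7) lists had camera adjusted p of 0.618, 0.668, 0.668, 0.188 and 0.92, and vit-2 had 44.4 ± 26.5 FPKM (adjusted p = 0.832). Neuron rises numbered 1 without any 1 of the EV 15C libraries, EV 20C replicate 3, iff-1 RNAi 15C replicate 1 or iff-1 RNAi 15C replicate 2. Without EV 15C replicate 3 camera called the immune list higher (median 0.49 instead of 0.27, adjusted p = 0.0254) and the intestine list higher (0.75 instead of 0.21, adjusted p = 0.0333). The cuticle median was then 0.32 instead of 0.12. The library iff-1 RNAi 15C replicate 1 stood apart in its group, with a mean log2 level of 3.246 for the cuticle list against 2.515 and 2.67 and 4.71 for the intestine list against 3.91 and 4.09. Called muscle falls numbered 1 without EV 15C replicate 1, EV 15C replicate 3, iff-1 RNAi 15C replicate 1 or iff-1 RNAi 15C replicate 2. Under both comparisons the lists of pharynx, early embryonic, and coelomocyte and uterus genes had fewer than 5 tested members, 1, 3 and 1, and were not tested as lists.

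Among the 10 largest rises under iff-1 RNAi 4 genes are protein-coding: snpc-1.3, fog-3, ZK177.9 (from 0.59 ± 0.15 to 3.38 ± 0.716 FPKM) and CD4.1 (from 0.77 ± 0.149 to 3.48 ± 0.473). K07C5.12 and WBGene00012620 are listed at 0 in all EV 15C libraries. Among the 10 largest falls 8 are protein-coding, and besides iff-1 they include the mitochondrial ATPase gene atad-3, from 105 ± 0.668 to 53.2 ± 5.10 FPKM, the short-chain dehydrogenase gene dhs-12, from 87.0 ± 0.744 to 44.4 ± 1.48, apm-3, from 9.29 ± 0.522 to 3.84 ± 0.132, and M04B2.4, from 37.6 ± 1.55 to 19.8 ± 1.66.

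Of the genes called under iff-1 RNAi, 2653 had no overlap between the groups; of all genes 49.7% had none, against 10% by chance. With an estimated correlation 0 of 24 lists were called where camera's preset called 6, 1 higher and 5 lower; fry called 6 and its mixed form 20. Without EV 15C replicate 3 the preset called 10 lists, 4 higher and 6 lower. The immune, intestine, fatty acid (adjusted p = 0.0405) and oxidative phosphorylation (adjusted p = 0.0254) lists were added.

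**Figure D2:**
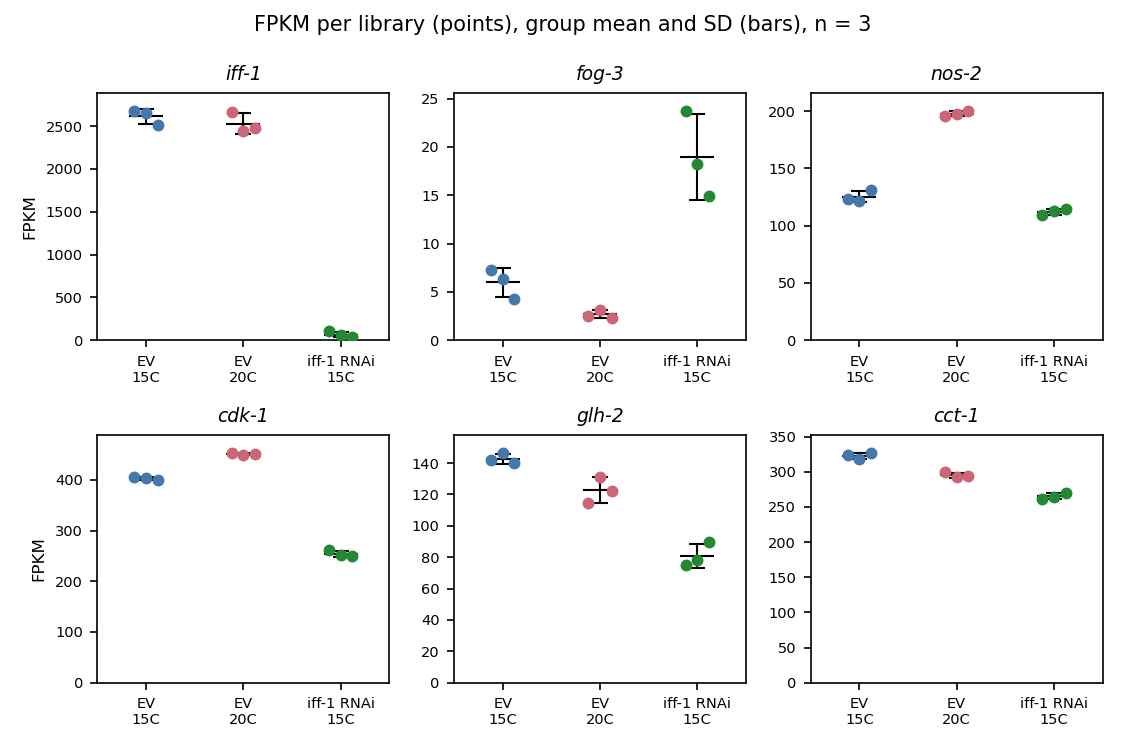
FPKM of 6 genes in each of the 9 libraries (points), with the mean and SD of each group (bars, n = 3) and a linear axis from 0. The iff-1 RNAi 15C libraries lie at 37.4 to 103.9 FPKM for iff-1, and their means lie above EV 15C for fog-3 (18.96 against 5.98 FPKM) and below it for cdk-1 (254 against 403), glh-2 (80.8 against 142.7) and cct-1 (265 against 323).

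Setting iff-1 RNAi 15C directly against EV 20C tests where the responses to the 2 conditions differ. With camera's preset correlation the lists of DNA replication, mitotic and oogenesis genes were called lower under iff-1 RNAi at 15°C than at 20°C on empty vector, and the list of ribosomal protein genes higher. None of these 4 was called with an estimated correlation (adjusted p = 0.547, 0.547, 0.838 and 0.838), and under quantile normalization 27 ribosomal genes were higher and 21 lower. Of 8572 genes 4193 differed, 1759 higher and 2434 lower under iff-1 RNAi, but with no filter on low values 2318 were higher and 2235 lower. The gene cdk-1 was lower (log2 -0.82, SE 0.02, limma adjusted p = 1.46e-06), as were nos-2 (-0.81, adjusted p = 7.43e-06) and sygl-1 (-0.59, adjusted p = 6.42e-05), while fog-3 was higher (2.42, adjusted p = 7.85e-05), so that the opposite changes of these 4 genes in the separate comparisons differed by test. The genes glp-1 (0.16), gld-1 (0.20) and hsp-4 (0.30) were higher, and cbs-1 (-0.94) and rpn-6.1 (-0.15) were lower. Among the 5 largest falls were spp-9 (-3.99) and the lectin gene clec-266 (-1.96), and of the 5 largest rises 0 were in protein-coding genes.

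Of 33 DNA replication genes 21 were lower and 2 higher under iff-1 RNAi than in EV 20C, or 22 and 2 adjusted over the list alone (camera adjusted p = 0.000375), and of 42 mitotic genes 24 and 2, the same adjusted over the list alone (0.000375). Of 30 oogenesis genes 17 were lower and 2 higher (camera adjusted p = 0.0043), and of 33 proteasome genes 20 and 1 (0.000727). Under quantile normalization 12 proteasome genes were lower and 2 higher, and neither list was called (adjusted p = 0.0639 and 0.091). Of 80 ribosomal protein genes 53 were higher and 2 lower (camera adjusted p = 7.89e-10), but under quantile normalization 27 were higher and 21 lower and the list was not called (adjusted p = 0.492, against a range of 8.56e-21 to 0.492 over the alternatives). The immune (5 of 13 higher), mitochondrial genome (6 of 12), intestine (3 of 15 higher, 1 lower) and cuticle (6 of 8 higher) lists had camera adjusted p of 0.0262, 0.0348, 0.0433 and 0.0135. The higher cuticle genes numbered 3 without EV 20C replicate 1, EV 20C replicate 3 or iff-1 RNAi 15C replicate 1, and the higher intestine genes 5 without EV 15C replicate 3, 7 without EV 20C replicate 2, 0 by limma without EV 20C replicate 3 and 1 without iff-1 RNAi 15C replicate 1. The immune call was lost without EV 20C replicate 1 (adjusted p = 0.0545) or iff-1 RNAi 15C replicate 1 (0.0556). The mitochondrial call was lost without EV 20C replicate 2 (0.086), and the intestine call without EV 20C replicate 1 (0.18), EV 20C replicate 3 (0.0903) or iff-1 RNAi 15C replicate 1 (0.13). With an estimated correlation 0 of the 9 called lists passed, with adjusted p between 0.547 and 0.838; fry called 11 and its mixed form 22. The other 15 lists had camera adjusted p between 0.123 and 0.991, including TRiC/CCT (5 of 8 lower, 1 higher) and germ granule genes (12 of 24 lower, 5 higher).

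Of 942 genes called both at 20°C and under iff-1 RNAi 542 changed the same way, 366 higher and 176 lower in both, and 400 the opposite way, 304 of them higher at 20°C and lower under iff-1 RNAi. With 1 library left out, the genes changed the same way numbered 280 (without EV 15C replicate 2) to 551 (without EV 20C replicate 1). Independent lists would share 264.7 genes higher in both, 112 lower in both, 249 higher at 20°C and lower under iff-1 RNAi, and 119.1 the other way, where 96 were seen. Because both comparisons use the same EV 15C libraries, unchanged groups would give correlated log2 fold changes across genes. The observed Pearson correlation was 0.18, against 0.50 in the simulations, and the Spearman correlation was -0.04, against 0.44. The covariance was 0.0251 against 0.0435 for unchanged groups, a difference of -0.0184, and 50.7% of genes had the same sign against 66.6%. The highest simulated covariance was 0.0735. The simulations gave all 3 groups 1 pooled spread, although EV 15C had the lowest median coefficient of variation (4.49%, against 6.43% and 5.57%). The shared part comes from EV 15C alone, so these simulated values may be too high. They also hold no changed genes, so they cannot tell whether the 2 responses are less alike than shared controls would make them. Simulated unchanged groups gave 0 genes called in both with the same direction. That follows from simulating no change in either comparison, so it gives no expected overlap for the 942 genes. The 3 control libraries cannot be split into separate sets of at least 2, so part of any excess over independent lists may come from the shared controls. The CCT list (8 and 7 of 8 fell) and the proteasome list (12 and 21 of 33 fell) were called lower in both comparisons by camera's preset but not with an estimated correlation (adjusted p = 0.225 and 0.222 for CCT, 0.30 and 0.061 for the proteasome). The genes cdk-1, nos-2 and sygl-1 rose at 20°C and fell under iff-1 RNAi, where the call of sygl-1 was lost without EV 15C replicate 1 (adjusted p = 0.0506).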

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

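The settings below were fixed before the values were seen, except 2 that were added afterwards and are named as such. Array weights gave 4962 genes called in EV 20C against EV 15C (2401 without weights) and 1184 shared genes (542 without). A fold threshold of 2 left 61 genes at 20°C, 33 under iff-1 RNAi, 197 in the direct comparison and 4 shared, which follows from its construction. With an estimated correlation camera called 0 lists at 20°C and 0 under iff-1 RNAi, where fry called 9 and 6. Leaving out 1 library gave 1521 genes (without EV 15C replicate 2) to 2503 (without EV 20C replicate 1) at 20°C, with 1534 without EV 15C replicate 1 and 1534 without EV 20C replicate 3, and 1787 to 3074 under iff-1 RNAi. The shared genes then numbered 280 (without EV 15C replicate 2) to 551 (without EV 20C replicate 1), and the lists called under iff-1 RNAi 5 (without iff-1 RNAi 15C replicate 2) to 10 (without EV 15C replicate 3). The cause of these changes was not tested. The log2 fold change of iff-1 stayed between -5.78 and -5.05. Blocking on the replicate number gave 2158 and 2425 genes, 469 shared and 12 and 6 lists. In 0 of 9 libraries was the best correlated library of both other groups the one with the same number. Best matches in only 1 other group were not counted. The settings added afterwards, protein-coding genes of at least 300 nt and exact 0 values as missing, gave 2443 and 2433 genes at 20°C and 2684 and 2676 under iff-1 RNAi. Of 210 called values of named genes 166 were kept in every fit with 1 library left out that tested them, 44 were lost in some, and 0 reversed direction. Without EV 15C replicate 1 only 207 of them were tested, and without EV 15C replicate 2 only 206.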

Other observations

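Many genes of the mitochondrial ribosome, a group not fixed in advance, fell under iff-1 RNAi. Classes of genes sharing a symbol prefix were tested after the data were seen, 95 classes of at least 8 members. The 570 Fisher's exact tests, of genes that are not independent, were one-sided and run separately for higher and lower genes, and 12 passed. Of 40 mrpl genes (large subunit) 25 fell under iff-1 RNAi (adjusted p = 1.76e-07, median -0.23), and of 29 mrps genes (small subunit) 18 fell (adjusted p = 1.86e-05, median -0.30), where 18.2% of the protein-coding genes with such symbols fell. The called rises in these classes were mrpl-50 (0.18, adjusted p = 0.0104), mrps-11 (0.14, adjusted p = 0.0192) and mrps-18A (0.11, adjusted p = 0.0427). The gene mrps-22 fell from 61.6 ± 0.819 to 36.5 ± 2.42 FPKM (SD, n = 3; limma adjusted p = 8.78e-05) and mrpl-22 from 57.5 ± 2.37 to 31.5 ± 4.24. At 20°C they differed by -0.01 and -0.03 (adjusted p = 0.935 and 0.836). Of 8 acdh genes, for acyl-CoA dehydrogenases of mitochondrial fatty acid oxidation, 6 fell under iff-1 RNAi (adjusted p = 0.0377), among them acdh-12 (-0.40) and acdh-7 (-0.51). At 20°C 16 of 36 fbxa genes, for F-box proteins, rose, where 20.2% of the protein-coding genes with such symbols rose (adjusted p = 0.0389). The fbxa result was lost scaled without the 10 highest genes (adjusted p = 0.155) and in most fits with 1 library left out, up to adjusted p = 0.397 without EV 15C replicate 2. The acdh result was lost likewise (adjusted p = 0.142, and up to 0.183 without EV 20C replicate 3).

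Some long genes had values that exact 0 entries hid from the test. With these 0 entries as missing, a choice made after they were seen, the tubulin gene tbb-1 fell at 20°C (-0.14, adjusted p = 0.0137) and under iff-1 RNAi (-0.36, adjusted p = 0.000654). The leucyl-tRNA synthetase gene lars-1 fell in both (-0.38 and -0.39), and the small GTPase gene rab-14 rose at 20°C (0.45, adjusted p = 0.00292). The missing values were those of tbb-1 in EV 15C replicate 1 and iff-1 RNAi 15C replicate 3. For lars-1 EV 15C replicate 2 was missing, and for rab-14 EV 20C replicate 2. These groups therefore had fewer values than the others, and the genes were picked after their values were seen.

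The tests of exact zeros, the proteasome test without pas-5 and the gene classes were chosen after the result was seen. The predictions of the other tests were written before those tests were run. Splitting 3 against 3 libraries gives 10 splits, so a share under 0.1 cannot be reached. For EV 20C against EV 15C only 1 split, the real one, reached its number of called genes, and the highest other split called 1 gene. For iff-1 RNAi 15C against EV 15C that number was also 1 split with at most 2 genes in any other, and for iff-1 RNAi 15C against EV 20C again 1 with at most 2.

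Exact zeros stood in 121 genes that other libraries listed at 10 FPKM or more. In the 20 of 21 long protein-coding genes with more than 1 nonzero value, the nonzero libraries had a median coefficient of variation of 6.1%, against 8.42% for all tested genes at 10 FPKM or more, which is what failed estimates in the quantification would give for the set, though F23C8.14, with 172.6%, goes against it. Expression switched off between groups was argued against in these long genes as a set, since 0 of 21 had zeros filling a whole group and no other library. This rule passes over C36A4.10, listed at 0 in all EV libraries and at 18.2 and 16.6 FPKM in iff-1 RNAi 15C replicates 1 and 2. It also passes over pas-5 and F23C8.14, listed at 0 in whole groups and in further libraries. For these genes the question stays open. Of the 94 genes of other biotypes with a 0, 100% were under 300 nt, against 30.8% of the 133 such genes without a 0, so few fragments on short transcripts could contribute, although fragments per gene were not measured.

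The proteasome and CCT chaperonin lists were called lower in both comparisons with camera's preset, but not with an estimated correlation (adjusted p = 0.30 and 0.061 for the proteasome, 0.225 and 0.222 for CCT), and at 20°C, scaled without the 10 highest genes, 3 proteasome subunits fell and 3 rose. Among 10000 random lists matched for length and expression level, the proteasome median lay at percentile 0.28 at 20°C and 0.05 under iff-1 RNAi, and the CCT median at percentile 0 and 0.01, which argues against a trend with gene length and expression level. For a chance level of the shared control libraries, the gap between the lowest EV 15C list mean and the highest other mean was 0.215 for CCT, against a range of 0.04 among the controls. For the proteasome it was 0.046 against a range of 0.259, which leaves this open, because pas-5 is listed at 0 in 8 libraries. Without pas-5 it was 0.036 against 0.017. Only lists called lower in both comparisons were put to this test, so EV 15C means above the others were largely set in advance. The gaps therefore cannot exclude a chance level of the controls. Whether temperature and iff-1 RNAi lower these genes through a common route was not tested here.

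The cuticle, muscle and immune lists were called lower at 20°C with camera's preset but not with an estimated correlation (adjusted p = 0.492, 0.494 and 0.499), and without EV 15C replicate 3 the immune median was 0.20 with its call lost (adjusted p = 0.393) and 0 of 8 cuticle genes were called by limma. If less somatic tissue were carried along, these lists would vary together among libraries of 1 group. Deviations from the group means of the immune and cuticle lists correlated over 9 libraries (Pearson r = 0.885, exact permutation p = 0.00463, adjusted p = 0.00694, Spearman rho = 0.80, exact permutation p = 0.00463), so varying amounts of somatic tissue could contribute. With 216 orders, 0.00463 is the smallest p that this permutation test can give. Without the 2 farthest libraries, EV 20C replicate 2 and iff-1 RNAi 15C replicate 1, r was 0.936. That value keeps EV 15C replicate 3 and may rest on this 1 library. Its cuticle mean was 3.04 against 2.52 and 2.48 in the other EV 15C libraries, and its immune mean 3.31 against 2.43 and 2.27. For the muscle and cuticle lists r was 0.69 (exact permutation p = 0.12, adjusted p = 0.12, rho = 0.867, exact permutation p = 0.0324, r = 0.654 without the 2 farthest libraries), which leaves that pair undecided. The muscle list covers sheath as well as body wall muscle. With camera's preset it was also called lower under iff-1 RNAi (median -0.36), where the cuticle list was not called (median 0.12). A direct effect of temperature on these genes stays open.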
